A study of Mus musculus with 6 samples.

How the data were processed

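RNA was measured in 6 libraries, 3 NC and 3 MF, prepared from poly-A RNA per the labels' protocols. HISAT2 2.0.5, featureCounts and the mouse build mm10 are named in the submitters' processing notes, without their settings; the tool behind the authors' comparison is not given in the sources used here. Strand use in counting is also not given, so genes that overlap, and near-identical copies, are uncertain.

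Each deposited file holds the same 2031 genes. Per the file headers it gives a raw count per gene, an FPKM value, a normalized signal, and the authors' log2 fold change, p-value and adjusted p-value, with gene length as another column. The deposited count divided by the authors' normalized signal was constant within each library, and the deposited FPKM equalled the count per kilobase of gene length scaled to a constant library total. These ratios gave library totals of 15655958, 16110497 and 14929232 for NC replicates 1 to 3 and 19176383, 16801089 and 16276230 for MF replicates 1 to 3. The deposited genes take between 5.68% and 10.4% of these totals. At these depths 3 counts, the limit that a count of 0 allows, correspond to between 0.156 and 0.201 FPKM for a gene of 1 kb; such floors and intervals cover counting error alone. All deposited genes have an adjusted p of at most 0.0499 and an absolute log2 fold change of at least 1.001, so the authors had selected them. The authors' adjusted p-values, their ranks and p-values at the top 30 ranks gave 19069 as the number of tests the authors had made.

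Gene names came from the files, and 1982 IDs matched the mouse reference names; 4 names that had been turned into dates were restored by ID. There were 48 rows with no gene name, which took between 0.0134% and 0.0390% of the library totals and stayed out of the tests. Named genes with a mean of at least 0.5 FPKM over the 6 libraries were kept (1651), and 332 named genes fell below that filter.

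The design had been fixed for FPKM files with limma; because the files hold counts, edgeR's quasi-likelihood test (edgeR 4.0.16, R 4.3.3) on the counts was used in its place, as the design had provided, with the recovered library totals as library sizes, group as the only term, a two-sided test and Benjamini-Hochberg adjustment at 0.05. The design did not say over how many tests to adjust. Adjustment over the 19069 recovered tests was tried first and called 0 genes; adjustment over the 1651 tested genes, which called 1610, was made the reported one after both counts had been seen. It does not control the false discovery rate over the genome, since the genes were selected on the same libraries. In the adjustment over 19069 tests, ranks were counted among the deposited genes alone, so its adjusted p-values are upper bounds. The common biological coefficient of variation of these selected genes was 0.506.

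Of 48 gene lists written before the data were examined, 13 had at least 5 tested members and were tested with camera (limma 3.58.1) at a preset correlation of 0.01, adjusted over lists. The background of each test is the other tested genes, which are themselves selected, and 5 lists have no deposited member. Genes were named by a rule fixed in advance: the 12 largest rises and 12 largest falls with adjusted p under 0.05, no overlap of the groups and a mean of at least 2 FPKM in the higher group, without predicted gene models; up to 4 members of each list past the threshold; and 12 genes fixed by name. Folds come from edgeR's log2 fold change, except where a group had 0 counts (a bound against 3 counts over the group) or 1 to 3 counts (a ratio with an exact 95% interval).

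The replicate numbers are shared between groups. The deviations of same-numbered libraries from their group means correlated across genes at 0.37, 0.56 and 0.34 for numbers 1, 2 and 3. However, NC replicate 3 correlated more with MF replicate 1 (0.55). Deviations within a group cancel out for each gene, so a match of the replicate 2 libraries alone favours positive values among the others. The values therefore do not settle the pairs of numbers 1 and 3. Same-numbered libraries were still taken as pairs for the replicate block and the splits, while the reported test had group as its only term. This pairing comes from the values and not from a label. No pair of libraries agreed within sampling noise, with chi-square per degree of freedom from 23.5 to 757.

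Alternatives were other pseudocounts, filters, scalings, variance models, a replicate block and each library left out in turn. DESeq2 1.42.0, TMM and the adjustment over recovered tests were added after the data had been seen. So were Fisher's test of list splits and leaving out both replicate 2 libraries. The test that the design had fixed for FPKM files, limma on log2(FPKM + 1), became an alternative because the files hold counts. Sample weights in limma stopped before full convergence. The pipeline was tested on simulated data for the 1651 tested genes at the estimated dispersions, with 200 of them changed. It called 6 of 100 genes changed 2-fold and 63 of 100 changed 4-fold, with 4 calls among 1451 unchanged genes and median absolute log2 fold changes of 1.07 and 2.12; with 0.25 times the dispersion it called 52 and 98, with 13 among the unchanged. Permutation tests and Fisher's exact test used scipy 1.17.1, and tables used pandas 2.3.3 and numpy 2.4.6 under Python 3.11.15.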

Results

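Gene expression was measured by RNA sequencing in cells differentiated from J1 mouse embryonic stem cells, a line of the 129S4/SvJae strain that can be induced towards heart muscle. The cells were grown as embryoid bodies, which are cell aggregates formed here in hanging drops over 3 days. The control group (NC, 3 libraries) was kept in a conventional incubator and the exposed group (MF, 3 libraries) in an incubator with a static magnetic field. The series describes the libraries as biological triplicates, and the field strength, the exposure time and the day of collection are not given in the sources used here. The library totals recovered from the deposited values lay between 14929232 counts in NC replicate 3 and 19176383 counts in MF replicate 1. The table analysed holds 2031 genes, every one of them past the authors' own thresholds for a difference between MF and NC, with an adjusted p of at most 0.0499 and an absolute log2 fold change of at least 1.001 in the authors' deposited table. Genes outside that selection were not analysed here, so no share of all genes, and no statement that a gene did not change, can be drawn from these values.

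The comparison asked which genes differed between cells cultured with and without the magnetic field. Heart muscle genes, regulators of the forming heart, collagen and mesenchyme genes, Hox genes and interferon-response genes were higher in MF, and genes of naive pluripotency and of germ cells were lower. Each statement covers the deposited members of a gene list alone, which are 9 of 27 for naive pluripotency. The camera test called 9 lists at a preset correlation and 0 at an estimated one. The authors' deposited table lists 1284 genes as higher and 747 as lower in MF. Of the 1651 named genes with a mean of at least 0.5 FPKM, 1026 rose and 584 fell in MF by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment over those 1651 genes, and 1025 and 584 of them by at least 2-fold. Because the genes had been selected for a difference on these same libraries, that adjustment does not control errors over the genome, and "rose" and "fell" are used below in this sense alone. With 1610 of the 1651 tested genes called, a call of every member of a list, also when adjusted over the list alone, is no added support. Of all deposited genes 63.2% are higher in MF, the share to set beside the direction of a list. Adjusted over the 19069 tests recovered from the authors' adjusted p-values, edgeR's test called 0 genes, with a smallest adjusted p of 0.0561, while 1613 genes had an unadjusted p under 0.05. Over the same 19069 tests, DESeq2 called 479 genes higher and 119 lower, and edgeR with the replicate number as a block called 376 higher and 128 lower. Ranks in these adjustments were counted among the deposited genes alone. The adjusted p-values are therefore upper bounds, and the counts, 0 included, are lower bounds.

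**Figure D1:**
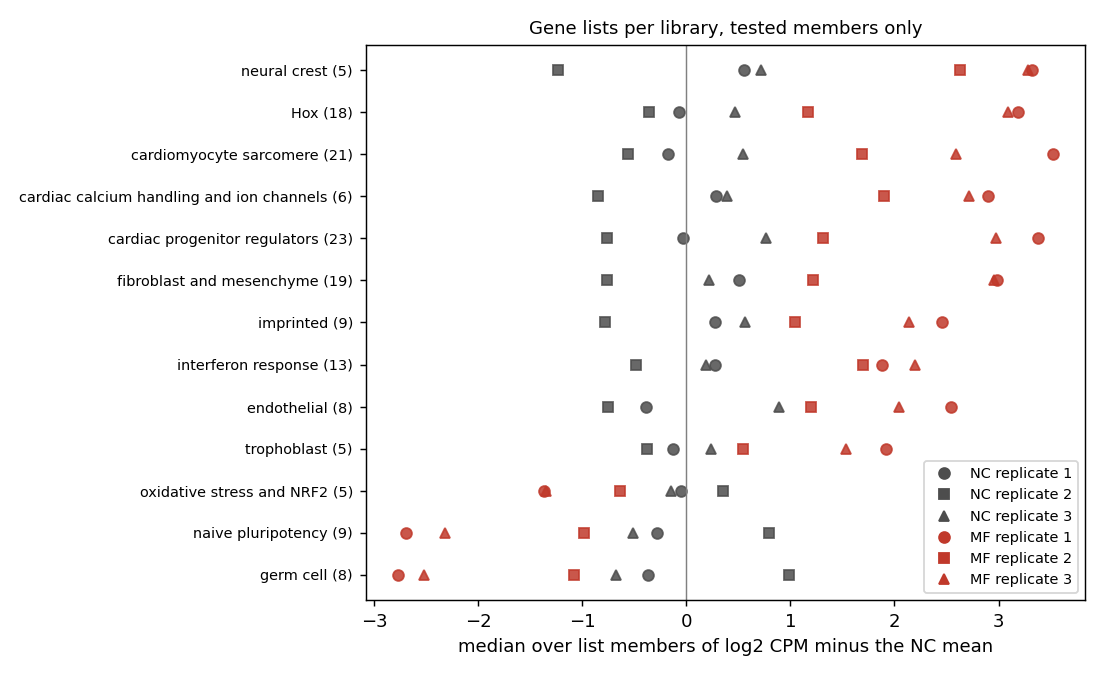
Median over the tested members of each gene list of log2 CPM minus the NC mean (horizontal axis), for each of the 6 libraries; the number of tested members follows each list name. NC replicates are grey and MF replicates red. MF replicate 2 lies nearer to NC than the other MF replicates in each list drawn, with a median of 1.32 for cardiac progenitor regulators against 3.38 and 2.98.

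Regulators of heart formation were higher in MF throughout the deposited part of their list. All 24 deposited members of the 32 listed cardiac progenitor regulators were higher, and all 23 that were tested rose, both over all tested genes and adjusted over the list alone. Tbx5, a transcription factor of the first heart field (mm10 chromosome 5, 119832668 to 119885219), rose 62.5-fold, from 0.0329 ± 0.0336 FPKM in NC to 2.13 ± 1.78 in MF (SD, n = 3; log2 fold change 5.97, SE 1.19, adjusted p = 0.0119). Hand2, a transcription factor needed for the ventricles (mm10 chromosome 8, 57320983 to 57324633), rose 32.1-fold from 1.25 ± 1.49 to 40.0 ± 31.9 FPKM. Its NC mean rested largely on NC replicate 3, at 2.96 FPKM against 0.543 and 0.238, and MF replicate 2 was close to that value at 3.11 FPKM. Tbx2 rose 16.1-fold, and Wnt2, a secreted signal, rose 47.6-fold although MF replicate 2, at 0.26 FPKM, lay below NC replicate 1 at 0.28 FPKM. The list was higher than the other tested genes by camera with a preset correlation (adjusted p = 0.000654), but not with an estimated correlation (adjusted p = 0.512). The list median was 1.32 log2 units above the NC mean in MF replicate 2, against 3.38 and 2.98 in MF replicates 1 and 3, and NC replicate 2 was lowest at -0.76.

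Genes of the cardiomyocyte sarcomere were higher in MF as well, while the 2 deposited skeletal muscle genes, Mylpf and Myh3, fell 6.40-fold and 7.56-fold. All 25 deposited members of the 35 listed sarcomere genes were higher, and all 21 tested members rose, also adjusted over the list alone. Myh6, the alpha cardiac myosin heavy chain (mm10 chromosome 14, 54941921 to 54966927), rose 16.2-fold from 1.19 ± 0.266 to 19.2 ± 10.3 FPKM (SD, n = 3; log2 fold change 4.02, SE 0.51, adjusted p = 0.00486). Tnnt2, cardiac troponin T, rose 11.4-fold from 0.985 ± 0.733 to 11.2 ± 7.05 FPKM, and Actc1, cardiac alpha-actin, rose 5.81-fold from 25.4 ± 15.1 to 147 ± 92.9 FPKM. Myl2, the ventricular myosin light chain, rose 31-fold, Tcap 16.2-fold and Tnni1 11.9-fold. The sarcomere list passed camera with a preset correlation (adjusted p = 0.000591) and not with an estimated correlation (adjusted p = 0.512). Its median in MF replicate 2 was 1.68 log2 units above the NC mean, against 3.52 and 2.59 in the other MF libraries. Single members differed in this. Among the MF libraries, Myl2 and Tcap were highest in replicate 2, at 15.6 and 3.96 FPKM, and lowest in replicate 3, at 1.70 and 1.10 FPKM. Myh6 and Tnni1 were lowest in MF replicate 2, at 10.8 and 3.37 FPKM. Cox6a2, a heart and skeletal muscle subunit of cytochrome c oxidase (mm10 chromosome 7, 128205435 to 128206387), had 0 counts in all NC libraries. It stood at 6.67 ± 3.73 FPKM in MF, at least 70.3-fold higher against a floor of 3 counts over the NC group. Among the MF libraries it was also highest in replicate 2, at 10.9 FPKM against 5.44 and 3.70 in replicates 1 and 3. All 12 deposited members of the list of cardiac calcium handling and ion channels were higher and all 6 tested members rose, among them the sodium-calcium exchanger Slc8a1 (14.5-fold) and the pacemaker channel Hcn4 (6.75-fold). This list passed camera with an adjusted p of 0.0254 and not with an estimated correlation (adjusted p = 0.512), nor in limma with a pseudocount of 0.1 (0.0507) or sample weights (0.0643), nor in Fisher's exact test of the split (0.134).

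**Figure D2:**
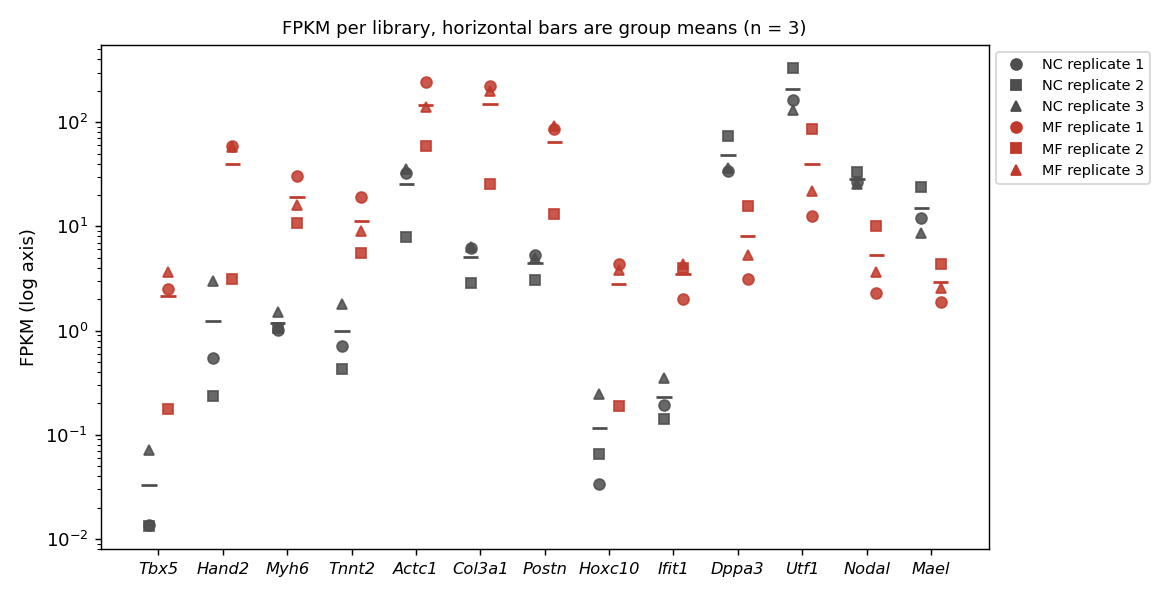
FPKM on a log axis for 13 genes named in the text, one point per library, NC in grey and MF in red, with a horizontal bar at each group mean of 3 libraries. Myh6 lay between 1.02 and 1.49 FPKM in NC and between 10.8 and 30.7 FPKM in MF; for Hoxc10 the MF replicate 2 value of 0.19 FPKM fell within the NC range.

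Matrix and mesenchyme genes showed large rises. All 19 deposited members of the 23 listed fibroblast and mesenchyme genes rose, over all tested genes and adjusted over the list alone. Lum, the matrix proteoglycan lumican, rose 89.1-fold from 0.252 ± 0.260 to 22.5 ± 18.97 FPKM (SD, n = 3; log2 fold change 6.48, SE 1.24, adjusted p = 0.0111). Col3a1, a chain of fibrillar collagen (mm10 chromosome 1, 45311538 to 45349706), rose 29.2-fold from 5.10 ± 1.97 to 149 ± 108 FPKM. Postn, periostin, rose 14.4-fold and Dcn, decorin, 20.6-fold. The list passed camera with a preset correlation (adjusted p = 0.000654) and not with an estimated correlation (adjusted p = 0.512). MF replicate 2 stood at 1.22 log2 units against 2.98 and 2.96 in the other MF libraries.

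All 22 deposited Hox genes, transcription factors of axial position, were higher in MF, and 17 of the 18 tested members rose, also adjusted over the list alone. Hoxc10 rose 23.8-fold from 0.115 ± 0.114 to 2.79 ± 2.27 FPKM, with overlapping groups. Hoxc8 had few counts in NC, and its ratio of counts was 84.0 with a counting interval from 22.9 to 699. The Hox list passed camera with an adjusted p of 0.00411 and not with an estimated correlation (adjusted p = 0.512), and its median in MF replicate 2 was 1.17 against 3.18 and 3.09. All 5 deposited neural crest genes rose, including Ednrb (9.11-fold), Foxc2 (8.93-fold) and Snai2 (8.43-fold). That list passed camera at an adjusted p of 0.0416 and not with an estimated correlation (adjusted p = 0.512); without MF replicate 2 its adjusted p was 0.103, without both replicate 2 libraries 0.0688, in limma with a pseudocount of 0.1 or sample weights 0.0534 and 0.0844, and in Fisher's exact test of the split 0.182.

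Interferon-response genes were higher in MF by a similar amount in each exposed library. All 13 deposited members rose, also adjusted over the list alone, with list medians of 1.88, 1.70 and 2.20 log2 units above the NC mean in MF replicates 1, 2 and 3. Ifit1, an interferon-induced RNA-binding protein (mm10 chromosome 19, 34640871 to 34650009), rose 14.97-fold from 0.229 ± 0.111 to 3.45 ± 1.25 FPKM (SD, n = 3; adjusted p = 0.0111). Ifit3 rose 7.04-fold, Usp18 6.996-fold and Rtp4 4.63-fold. Camera gave the list an adjusted p of 0.00799 with a preset correlation, and the adjusted p was 0.512 with an estimated correlation. It was 0.0700 without both replicate 2 libraries and 0.0819 with a filter at 2 FPKM.

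Genes of naive pluripotency fell. All 9 deposited members of the 27 listed genes fell, also adjusted over the list alone. Dppa3, a marker of naive stem cells and early germ cells (mm10 chromosome 6, 122626410 to 122630272), fell 5.96-fold from 48.0 ± 22.2 to 8.05 ± 6.70 FPKM (SD, n = 3; log2 fold change -2.58, SE 0.64, adjusted p = 0.0170). Utf1, a chromatin factor of pluripotent cells, fell 5.23-fold from 209 ± 110 to 40.1 ± 39.9 FPKM, and Prdm14 fell 6.32-fold. All 8 deposited germ cell genes fell, with Mael, a piRNA pathway factor, going 5.12-fold from 14.9 ± 7.98 to 2.92 ± 1.27 FPKM and Asz1 falling 13.0-fold. Camera gave adjusted p-values of 0.000591 for pluripotency and 0.000881 for germ cells; with an estimated correlation the adjusted p was 0.512 for each. The direction test fry gave adjusted p-values of 0.0501 and 0.0544. NC replicate 2 had the highest list medians, 0.80 and 0.99 log2 units above the NC mean, and MF replicate 2 stood at -0.99 and -1.08 against values from -2.77 to -2.31 in the other MF libraries.

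Some genes in lists of early embryonic patterning and signalling also differed, in both directions. Nodal, a signal of the primitive streak, fell 5.31-fold from 28.3 ± 4.10 to 5.32 ± 4.13 FPKM (SD, n = 3; adjusted p = 0.0153). Of the 2 deposited Nodal and TGF-beta targets, Lefty2 fell 6.81-fold and Tgfbi rose 3.14-fold, from 27.1 ± 11.5 to 85.2 ± 33.9 FPKM. Eomes fell 4.01-fold and the Nodal cofactor Foxh1 3.57-fold. Evx1 rose 6.13-fold with overlapping groups, as MF replicate 2 at 0.559 FPKM lay below NC replicate 3 at 0.675 FPKM. Etv4 and Etv5, readouts of FGF signalling, fell 3.06-fold and 3.02-fold. The 3 deposited BMP targets Bambi, Atoh8 and Msx1 rose 3.06-fold, 3.94-fold and 7.75-fold, with overlapping groups for Msx1. The Notch targets Hey2 and Hey1 rose 6.71-fold and 2.69-fold. Of the 3 deposited Wnt targets, Nkd1 rose 4.62-fold, Apcdd1 rose 2.15-fold and Tcf7 fell 2.21-fold. These lists had fewer than 5 tested members and were not tested as lists.

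Lists that did not pass the list test had members going both ways or smaller changes. Of the 9 deposited imprinted genes 7 rose and 1 fell; Plagl1 rose 21.1-fold from 3.93 ± 1.67 to 82.9 ± 60.4 FPKM and Igf2 rose 4.82-fold. Camera gave this list an adjusted p of 0.0912, and the adjusted p was 0.553 with an estimated correlation. It was 0.0374 with the replicate number as a block, 0.0379 without MF replicate 2, 0.0424 without both replicate 2 libraries and 0.0397 with quantile normalization. Of 8 endothelial genes 7 rose, including Cd34 (4.56-fold), and Pecam1 fell; camera gave an adjusted p of 0.204 (0.553 with an estimated correlation) and fry 0.0476. All 5 deposited trophoblast genes rose, with Peg10 going 2.67-fold from 172 ± 33.2 to 459 ± 184 FPKM, and the adjusted p was 0.229 by camera (0.553 with an estimated correlation) and 0.0460 by fry. Of 5 genes of the oxidative stress response 4 fell, among them Nqo1 (2.37-fold, from 17.0 ± 2.01 to 7.15 ± 1.08 FPKM), and camera's adjusted p was 0.0527, or 0.512 with an estimated correlation. It was 0.0379 without MF replicate 2, 0.0424 without both replicate 2 libraries, 0.0437 with median-of-ratios scaling, 0.0385 with TMM and 0.0487 in limma on log2(FPKM + 1), and fry gave 0.0386. Per2 of the circadian clock rose 2.44-fold and Ciart fell 3.04-fold over all tested genes, but neither passed when adjusted over the list alone. Of the 12 genes fixed in advance, Tbx5, Myh6, Tnnt2 and Actc1 are given above. The others, Pou5f1, Nanog, T, Mesp1, Nkx2-5, Gata4, Cry1 and Cry2, are outside the authors' selection and were not analysed here. The directions given above for cardiac and pluripotency genes do not cover them.

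Further genes with the largest changes included Hspb7, a small heat shock protein of heart muscle, which rose 47.3-fold from 0.107 ± 0.0317 to 5.22 ± 1.56 FPKM (SD, n = 3; adjusted p = 0.00486). Fmod rose 55.7-fold, Col14a1 39.1-fold, Sphkap 44.3-fold and Igfbp1 34.9-fold. MF replicate 2 was the lowest MF library for each of them. It stood at 0.126, 0.297 and 0.174 FPKM for Fmod, Col14a1 and Sphkap, against highest NC values of 0.0563, 0.134 and 0.140. Igfbp1 stood at 18.3 FPKM in MF replicate 3, against 3.66 and 1.95 in MF replicates 1 and 2. Lrrc17 had 1 count over the NC libraries, with a ratio of 486 and a counting interval from 86.9 to 19236. Among the largest falls, Stra8, a factor of meiotic entry, went 22.4-fold from 28.0 ± 25.8 to 1.25 ± 1.31 FPKM, Sohlh2 fell 14.5-fold and Tuba3b 21.4-fold. Nlrp4c fell 15.6-fold, Cyp2b23 13.3-fold, Khdc3 12.6-fold and Fxyd2 11.98-fold. NC replicate 2 was the highest NC library for Stra8, Sohlh2, Tuba3b, Nlrp4c, Khdc3 and, by little, Cyp2b23. For Sohlh2 it stood at 77.1 FPKM, against 15.9 and 17.5 in NC replicates 1 and 3. Fxyd2 was highest in NC replicate 3, at 5.32 FPKM against 1.90 and 0.821 in NC replicates 1 and 2. Ly6k had few MF counts, and its ratio of NC to MF was 98.5 with a counting interval from 17.2 to 3933. Dppa5c, Rhox2a, Xlr5c and Ctag2l1 also fell, but they have near-identical copies and their counts are uncertain. Predicted gene models that met the same rule, 23 higher and 71 lower, are not named.

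The counts of calls depended on which library was left out and on the scaling. Without MF replicate 3, edgeR called 12 genes higher and 0 lower, with 858 at an unadjusted p under 0.05; without MF replicate 1 it called 357 and 90, without NC replicate 1 422 and 219, without NC replicate 2 589 and 146, and without NC replicate 3 629 and 383. Without MF replicate 2 they were 996 and 582, close to the reported counts. Scaling on the deposited genes themselves gave 212 higher and 464 lower by median of ratios, 291 and 589 by TMM, 389 and 527 by quantile normalization, and 1048 and 206 with FPKM rescaled to equal sums, without a change of sign in any tested gene.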

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

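The 48 rows without a gene name were kept out of the comparisons, and 10 of them are higher in MF in the authors' deposited table, which makes them a signal in data outside the tests above the level in the control libraries; the other 38 are lower. They had been selected by the authors for a difference, as had every other deposited gene.

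The tests of MF replicate 2 in this part, and the test of an extra copy of chromosome 18, were chosen after the pattern had been seen; the protocadherin and gene length tests were fixed before their values were seen. MF replicate 2 lay between the groups: on a log2 scale where the NC mean is 0 and the mean of MF replicates 1 and 3 is 1, its median position over the tested genes was 0.535. A swap of labels with an NC library stays open. Each NC library was placed on a scale of its own, with the mean of the other NC libraries at 0. The highest median position of an NC library on such a scale was 0.210. However, genes selected under these labels place MF replicate 2 above the NC libraries whether or not labels were swapped. Lower depth is argued against by the library total of MF replicate 2, at 16801089 counts. It lay below that of MF replicate 1 (19176383) but above that of MF replicate 3 (16276230) and of every NC library. The 25% of genes with the most counts also had a median position of 0.486 (bootstrap interval 0.467 to 0.514). The bootstrap takes genes as independent. A single dilution of MF RNA with RNA like that of NC would move every gene by the same fraction of its abundance. On the linear CPM scale the interferon genes stood at a median position of 0.751, the fibroblast genes at 0.108 and the sarcomere genes at 0.350. The interferon and fibroblast genes differed by 0.643, the largest difference of 12 lists set against the fibroblast list (permutation test over genes, two-sided, adjusted p = 0.00072). A single dilution would not give this difference in unselected genes. These genes were selected on libraries that include MF replicate 2, however, which can favour genes where it lies far from NC. The test also takes the members of a list as independent. Whether dilution was the whole cause therefore stays open. A shift shared by both replicate 2 libraries stays open: NC replicate 2 also lay away from the MF side, at -0.43, and the median log2 difference between MF and NC in the direction of the change was 1.64 within number 2, against 1.79 and 1.61 within numbers 1 and 3. Of the 6 ways to pair the libraries 2, the numbered one included, gave pair medians as close together, too few ways for a share under 0.05, and no label says what libraries of one number share. A different course of differentiation, in that culture or in both of number 2, stays open and was not tested. Of the 1052 tested genes higher in MF, MF replicate 2 was over 2-fold below both other MF libraries in 300, against 8 and 2 such genes for MF replicates 1 and 3, and over 2-fold above both in 20, against 7 and 6; examples of the latter chosen after their values were seen are Mb, myoglobin, at 25.4 FPKM against 2.17 and 1.24, and Cd36 at 9.10 against 0.741 and 1.42.

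Chromosome 18 holds 62 deposited genes that are higher in MF and 5 that are lower, 92.5% against 62.2% elsewhere (Fisher's exact test, adjusted p = 7.97e-07 over 20 chromosomes). It was not the only skewed chromosome: chromosome 6 also leaned higher (75.9%, adjusted p = 0.0075), and chromosomes 11 (46.7%, adjusted p = 5.82e-05) and X (45.9%, adjusted p = 0.000182) leaned lower. The clustered protocadherin genes, whose models overlap, make up 19 of the higher genes on chromosome 18. Without them the share on chromosome 18 still exceeded the other chromosomes by 27.4 percentage points (89.6%, Fisher's exact test, p = 5.22e-05), so overlap in those clusters is argued against as the whole cause. An extra copy of the chromosome would add genes pushed just past the 2-fold limit; the higher genes there outside the clusters differed from those elsewhere by -0.13 in median log2 fold change (1.64 against 1.77, permutation p = 0.449), which leaves a gain of the chromosome open, untested by any measure of dose.

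The directions of the gene lists might follow gene length, since tested genes higher in MF are longer (median 5109 bases against 2411). Among tested genes matched on length, 71.2% were higher for the cardiac progenitor list and 77.2% for the fibroblast list, against 100% of the members. The largest permutation p over the cardiac progenitor, sarcomere, fibroblast, pluripotency and germ cell lists was 0.0047 (one-sided, 10000 draws). The draws take members as independent, while their estimated correlations lay between 0.361 and 0.912, so this p is too small. The shares go beyond length-matched genes, but whether length could give these directions stays open. RNA quality stays open: no measure of RNA integrity was analysed here, and some values that can move with it differ between the groups. Chosen after their values were seen, these are the 6 deposited genes of the mitochondrial genome, all lower in MF, 38 of 40 processed pseudogenes, also lower, and Gm23935, annotated as a miRNA gene, which fell 2.63-fold from 10955 ± 4886 to 4162 ± 664 FPKM (SD, n = 3, edgeR adjusted p = 0.0253).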

How the results depend on the processing

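The reported counts of 1026 genes higher and 584 lower depend most on the number of tests adjusted over, a choice made after both outcomes had been seen. Over the 19069 recovered tests edgeR gave 0 and 0, also at 2-fold or more, with 1613 genes at an unadjusted p under 0.05. Over the same tests DESeq2 gave 479 and 119, and the replicate block 376 and 128, with the same numbers at 2-fold or more. The counts are smaller because of the larger number of tests. They are also lower bounds, since ranks were counted among the deposited genes alone. With the replicate block and the reported adjustment the counts were 1030 and 590, and the block changed the call of 1 list, the imprinted genes. The block also ended the call of 3 of the 125 tested named genes. A filter at 2 FPKM gave 611 and 369, and 5 lists against 9, since fewer genes were tested. Median-of-ratios scaling gave 212 higher (204 at 2-fold or more), quantile normalization 389 (269) and TMM 291 (280), with median shifts of -0.82, -0.59 and -0.70 log2 units; these scalings assume that as many deposited genes rise as fall. FPKM rescaled to equal sums left 206 lower (206), with a shift of 0.25. At 2-fold or more, limma on log2(FPKM + 1) gave 598 and 378, without trend 598 and 372, and with sample weights 639 and 360, since the pseudocount shrinks low genes. Leaving out each library in turn gave from 12 to 996 higher and from 0 to 582 lower, and from 12 to 994 and 0 to 581 at 2-fold or more; the lowest are without MF replicate 3, where 121 of the 125 tested named genes lost their call. Camera with an estimated correlation called 0 lists, fry called 10 and Fisher's test of the split 7. Without both replicate 2 libraries, edgeR gave 1027 and 582, and 844 and 407 over the recovered tests. No tested gene changed sign under any alternative, which for genes selected at 2-fold says little. DESeq2, TMM, the adjustment over recovered tests, Fisher's test and leaving out both replicate 2 libraries were chosen after seeing the data. The test fixed in the design for FPKM files, limma on log2(FPKM + 1), was an alternative here because the files hold counts. On simulated data 6 of 100 genes changed 2-fold were called, and 52 with 0.25 times the dispersion. The simulation changed 200 of the 1651 genes, while 1610 were called in the data, so its rates do not describe the reported test. Depth was not varied, and a count of 0 allows up to between 0.156 and 0.201 FPKM for a gene of 1 kb.

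The 10 splits of the 6 libraries into groups of 3 are too few for a share under 0.05. The real split gave 1610 genes, the number of splits with as many was 1, and the highest other split gave 34; at 2-fold or more these were 1609, 1 and 34. Splits that part all 3 pairs, as the real one does, gave 0, 8 and 0 genes. For lists past the threshold, the real split gave 9, the highest other split also 9, and 3 splits reached it. The genes had been selected on the real split, so it is favoured by construction.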

Other observations

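Other families among the deposited genes also leaned one way; these were chosen after their values were seen, and counts are directions in the authors' deposited table. Of 60 homeobox transcription factors 54 are higher and 6 lower in MF (Fisher's exact test, adjusted p = 3.05e-05 over 8 families), but 22 of the 54 are the Hox genes described above. Without the Hox genes 32 are higher and 6 lower, a share of 84.2% against 62.4% of the deposited genes outside the family (Fisher's exact test, p = 0.00598). Collagen chains are higher in 19 cases and lower in 1, and the clustered protocadherins, which mark neurons by their cell surface, in 19 and 0. The 4 metallothioneins, which bind zinc and copper, are all lower; Mt1 fell 3.04-fold from 177 ± 63.3 to 58.2 ± 38.1 FPKM (SD, n = 3, edgeR adjusted p = 0.0265). Multicopy X-linked germline families are lower in each deposited member, with 8 Xlr, 5 Rhox and 5 Fthl17 genes, and their counts are uncertain. The 3 deposited members of the Y-linked list, which was fixed in advance, are lower too. Uba1y was tested and fell (log2 fold change -2.91). Kdm5d went from 0.228 FPKM in NC to 0.0234 in MF and Zfy1 from 0.781 to 0.0777, both below the filter. Of 40 processed pseudogenes 38 are lower, and all 6 deposited genes of the mitochondrial genome are lower.

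NC replicate 2 lay on the far side of the other NC libraries from MF. Its median position was -0.43 on the log2 scale from the mean of the other NC libraries to that of MF replicates 1 and 3. The test of this was chosen after the result was seen. A candidate explanation is that control cultures had differentiated to different extents. The smallest absolute list median of NC replicate 2 against NC replicates 1 and 3 was 0.863 log2 units over the pluripotency, germ cell, cardiac and fibroblast lists, each in the direction this needs. Other tested genes moved the same way, however, and no list exceeded the other genes of its direction after adjustment (permutation test, one-sided, adjusted p from 0.0939 to 0.277), so the values do not separate this hypothesis from a shift of all selected genes, nor from one shared with MF replicate 2.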
